A study of Homo sapiens with 9 samples.

How the data were processed

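RNA was measured by poly(A) RNA-seq in 9 libraries of MCF7 cells, with 3 libraries for each of 3 culture surfaces. Per the labels' protocols, RNA was extracted with QIAzol and libraries were made after NEBNext poly(A) selection. Trim Galore 0.6.7, STAR, DESeq2 1.36.0 and the hg38 genome are named per the submitters' processing notes, with no STAR version. The tool that counted reads per gene, the gene annotation, the strandedness and any filter on genes are not given in the sources used here. Because strandedness is not given, reads of a gene and of an antisense partner cannot be told apart here. Genes with near-identical copies, such as the AKR1C genes, the histone genes, the HLA genes, ribosomal protein genes with pseudogenes and the 7SL RNA genes, are uncertain where the counting could split their reads.

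The authors deposited a table of raw read counts per gene, with 1 column per library and 21692 genes, of which 3157 have no symbol. The lowest total of any gene over the 9 libraries was 16 counts, so genes with fewer counts are not in the table. A second deposited table holds a normalized signal, and its values are the counts of the first table divided by 1 size factor per library. Dividing out that factor gave values within 0.001 of a whole number in 100% of cases, and these, rounded, equalled the raw counts in 100%, so the count test ran on the raw table alone. Each of the 9 columns matched 1 sample by the code in its description, and 0 columns had no sample.

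Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates of a surface came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Counts of each pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom between 12.02 and 38.03, so no library was treated as a duplicate.

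Y-linked genes, XIST and TSIX were left out, which left 21674 genes. Counts were analysed with edgeR 4.0.16 in R 4.3.3, using TMM normalization, the filterByExpr filter by group (18767 genes tested) and the quasi-likelihood F test on all 9 libraries with the group as the only term. All 3 groups then share one estimate of the spread, with 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the tested genes, and an adjusted p under 0.05 passed. Each group was compared with each other group, which gave 3 comparisons. Log2 fold changes are given with their standard errors, and levels as counts scaled to a common library size (CPM) with the SD over 3 libraries, using TMM library sizes. Coordinates and gene types come from GENCODE release 29 on hg38, where 21584 of the 21674 identifiers were found.

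Gene lists were tested with camera (limma 3.58.1), with a preset correlation of 0.01 between members and again with an estimated correlation. P-values were adjusted over 31 lists and 3 comparisons, which makes 93 tests. The lists cover interleukin ligands, interleukin receptors, interleukin signalling, chemokines, NF-kappaB targets, interferon-stimulated genes, antigen presentation, estrogen-induced genes, luminal identity, basal and mesenchymal genes, YAP/TAZ targets, SRF/MRTF actin genes, integrins and focal adhesion, extracellular matrix, TGF-beta targets, mitosis, DNA replication, cholesterol synthesis, fatty acid synthesis, hypoxia, glycolysis, ATF4 targets, the unfolded protein response, heat shock, immediate early genes, p53 targets, ribosomal proteins, nuclear-encoded respiratory chain genes, mitochondrially encoded genes, replication histones and markers of other cell types. For each list the number of members that passed is given over all tested genes and again adjusted over the list alone.

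The groups, the designs, the lists, the first group of other settings listed further on and the rule for named genes were fixed before the data were examined. That rule names, per comparison, the 10 largest rises and the 10 largest falls among genes with a symbol that passed, had a mean of at least 1 CPM and did not overlap between the groups. Where no gene passes in a direction, the 5 with the smallest p are named as not passing. From each list described it takes 2 to 4 members with the smallest adjusted p, though for many lists fewer are printed here. A panel of estrogen-response, YAP/TAZ, interleukin, proliferation and sterol genes is tested whether it passes or not. Other genes, named because a count was 5 or fewer or because they stood out, were chosen after their values were seen.

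The groups share replicate numbers, so a fit with the replicate number as a block was chosen as a second fit. Whether the numbers pair the libraries was checked from deviations from the group means. Over all 18767 tested genes the correlation of same-numbered libraries ran from 0 to 0.5, against -0.42 to 0.21 for different numbers. In that check 6 of 9 libraries correlated best with their own number. Over the 14038 genes above 1 CPM in the R libraries, 32 kPa replicates 1 and 2, it ran from 0.32 to 0.64, against -0.48 to 0.02 for different numbers, and 9 of 9 libraries correlated best with their own number. Because a set of RNAs missing from the R libraries dominates the first check, the second was used and the numbers were taken to pair the libraries. The labels do not say what a number stands for. Blocked values are given for many, not all, of the calls and counts that they changed.

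The other settings chosen at that time were the size factors of DESeq2 in edgeR, no low-count filter, a filter of 1 CPM in 3 libraries, a fit on the compared groups alone, the replicate block, DESeq2 1.42.0 as the test, a term for the R libraries, leaving both out, an estimated correlation in the list test and leaving out each library in turn. Settings added after seeing the data were a covariate for the percent of counts in blood-cell genes, not log-transformed, and restricting the test to genes above 1 CPM in the R libraries. Each was run with and without the block. Joining the block with DESeq2, with the term for the R libraries, with leaving them out or with an estimated correlation was added then too. The filter on genes above 1 CPM looks at 2 libraries of the 32 kPa group and so also removes genes that fell there. It does not remove blood-cell reads from genes that the R libraries express too.

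The procedure was tested on simulated counts for TC against 0.5 kPa over 18356 genes. Without a shared batch, edgeR recovered 36.4% of genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 97% of those changed by 2, with 9 false calls among 146. With a batch shared by replicate number, over 18305 genes, the fit without the block recovered 9.1% of genes changed by 0.5 and the fit with it 28.8%. In a simulated list test, the 1 shifted list was called and 0 of the others. Total counts ran from 35.3 to 100.1 M per library. The binomial intervals are at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.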

Results

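MCF7 cells, an established estrogen receptor positive breast cancer line, were grown for 48 h on culture surfaces that differ in rigidity, and their polyadenylated RNA was sequenced. The medium was free of phenol red, held 10% charcoal-stripped serum, which is low in steroid hormones, and was supplemented with 10 nM estradiol. The surfaces were fibronectin-coated (4 ug/mL) rigidity plates of 0.5 kPa or of 32 kPa and normal tissue culture plates (TC), whose plastic is generally far stiffer than such gels. The labels describe the coating where they describe the rigidity plates, do not say whether TC plates had it and give no rigidity for TC, so comparisons with TC do not isolate rigidity. Each group had 3 libraries. Total counts for replicates 1, 2 and 3 were 43.2, 39.3 and 43 M on 0.5 kPa, 87.8, 100.1 and 43.8 M on 32 kPa, and 35.3, 37.6 and 40.4 M on TC. Replicates 1 and 2 on 32 kPa, the most deeply sequenced, carry sample codes ending in R, whose meaning the labels do not give, and are called the R libraries here.

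Transcripts known from blood cells were present in every library except those 2. A set of 188 genes, defined from the data, averaged above 1 CPM in the 7 other libraries and lay below 0.05 CPM in the R libraries. It is called the blood-cell set here, although its genes were chosen by these levels alone and not by cell type. CSF3R, the granulocyte colony-stimulating factor receptor, PTPRC, the leukocyte surface phosphatase CD45, ALAS2, the red-cell enzyme of heme synthesis, and CXCR2, a neutrophil chemokine receptor, are among its most abundant members. CSF3R reached 136 CPM on 0.5 kPa and 0.02 CPM in an R library. The set held 0.127% ± 0.0467 (SD, n = 3) of counts on 0.5 kPa, 0.0266% ± 0.0458 (SD, n = 3) on 32 kPa and 0.0553% ± 0.00496 (SD, n = 3) on TC. Within the 32 kPa group, replicate 3 had 0.0795% (95% interval 0.0786 to 0.0803), while the higher of the R libraries, replicate 1, had 0.00026% (95% interval 0.000225 to 0.000293). From 0.5 kPa to 32 kPa the median log2 fold change of these genes was -2.4, from 0.5 kPa to TC it was -1.19, and from 32 kPa to TC it was 1.18. All 188 moved in one direction in each comparison, and 0 of them passed the edgeR test in any. As the set was chosen for low levels in the R libraries, which are 2 of the 3 on 32 kPa, the size of its changes involving that group follows in part from the choice.

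**Figure D1:**
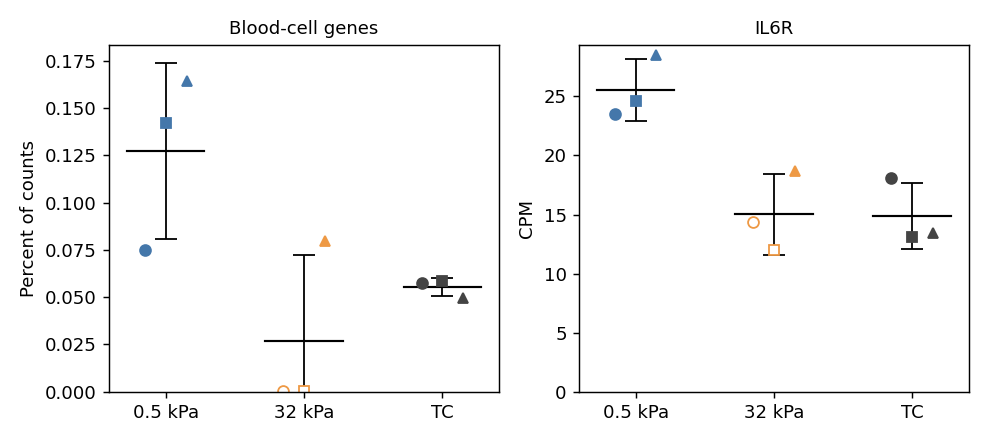
Left, percent of each library's counts in the 188 blood-cell genes. Right, IL6R level in CPM. Points are libraries of the 0.5 kPa, 32 kPa and TC groups (circle, square and triangle for replicates 1, 2 and 3, open symbols for the R libraries), and bars are the mean ± SD of 3 libraries. The R libraries lie near 0 on the left and at 13.1 CPM of IL6R when pooled on the right.

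Comparing 32 kPa with 0.5 kPa asks which genes respond to rigidity between gels of one kind, with the interleukin genes of the series title as the first question. IL6R, the interleukin 6 receptor, measured 15 ± 3.41 CPM (SD, n = 3) on 32 kPa and 25.6 ± 2.65 CPM (SD, n = 3) on 0.5 kPa, a log2 fold change of -0.77 (SE 0.18, edgeR adjusted p 0.49). The estrogen receptor gene ESR1 stood at 209 ± 30.5 CPM on 32 kPa and 191.9 ± 16.4 CPM on 0.5 kPa (SD, n = 3 each), and its target GREB1 at 1657 ± 39.8 and 1382 ± 133 CPM. YAP/TAZ targets, which rise on stiff surfaces in many cell types, had a median log2 fold change of 0.08 over 19 genes, with CCN1 at 0.39 (SE 0.2) and AMOTL2 at 0.13 (SE 0.08). None of these genes passed. In all, 0 of 18767 genes passed in edgeR, 1368 had an unadjusted p under 0.05, and DESeq2 called 159, of which 151 were lower on 32 kPa.

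Of 133 interleukin, receptor and signalling genes on the lists, 94 were in the table and 85 were tested, CXCL8 not being in the table. Over all genes 0 of the 85 passed, 15 had an unadjusted p under 0.05, and adjusted over the list alone 3 were lower on 32 kPa. These were the receptor genes IL6R and IL21R and the phosphatase gene PTPN6, and DESeq2 called the same 3. With the replicate number as a block, 0 passed over all genes, 12 were lower adjusted over the list alone, and 10 were lower over the genes above 1 CPM in the R libraries. IL21R measured 0.594 ± 0.181 CPM on 32 kPa and 1.63 ± 0.318 CPM on 0.5 kPa (SD, n = 3 each), and PTPN6 50.3 ± 0.689 and 62.1 ± 5.3 CPM. As a group the 33 interleukin receptor genes were lower on 32 kPa, with a median log2 fold change of -0.34 and 25 of 33 negative (camera adjusted p 2.22e-07, and adjusted p = 0.28 with an estimated correlation). Among them, 8 lay below 0.05 CPM in the R libraries and had a median of -2.38 (SD 0.43), 4 between 0.05 and 1 CPM had a median of -1.9, and 21 above 1 CPM had a median of -0.06 (SD 0.33). Choosing genes by their level in these libraries itself favours falls in the first of these sets and removes them from the last. IL1R2, IL2RG, IL7R, CXCR1 and CXCR2 are in the blood-cell set. With the block, the list test on the genes above 1 CPM gave an adjusted p of 0.0665. Over all genes the receptor list lost its call with a covariate for the blood-cell share (adjusted p 0.634) and with the block and the covariate (0.522), where the median of the 33 was -0.03. The gp130 gene IL6ST (log2 fold change -0.06, SE 0.11), IL1R1 (-0.14, SE 0.22), IL1RAP (-0.38, SE 0.17), IL17RB (0.24, SE 0.17), the ligand genes IL20 (-0.07, SE 0.21) and IL24 (-0.02, SE 0.39), STAT3 (0.03, SE 0.06) and SOCS3 (-0.1, SE 0.18) did not pass, with edgeR adjusted p between 0.675 and 0.993.

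Other immune lists were lower on 32 kPa too, while the blood-cell genes fell in share as given above. Of 15 antigen presentation genes, 14 were negative, with a median of -0.51 (camera adjusted p 1.93e-11, and adjusted p = 0.241 with an estimated correlation). None passed over all genes and 7 were lower adjusted over the list alone. Among them were HLA-A, a class I chain at 52.1 ± 8.19 CPM on 32 kPa and 74.1 ± 5.37 CPM on 0.5 kPa, and HLA-F at 10.1 ± 1.12 and 17.5 ± 2.48 CPM (SD, n = 3 each). Interferon-stimulated genes had a median of -0.24 over 38 (camera adjusted p 2.39e-08, and adjusted p = 0.28 with an estimated correlation), and IFITM2 measured 29 ± 7.68 and 45.1 ± 6.94 CPM. Of these 38, 0 passed over all genes and 4 were lower adjusted over the list alone. For NF-kappaB targets the median was -0.38 over 18 genes (camera adjusted p 2.44e-07, and adjusted p = 0.282 with an estimated correlation), with 0 passing and 3 lower adjusted over the list alone. Among them BIRC3, an inhibitor of apoptosis, measured 0.651 ± 0.478 and 2.69 ± 0.638 CPM. The basal and mesenchymal list had a median of -0.25 over 15 (camera adjusted p 0.0164, and adjusted p = 0.241 with an estimated correlation). Its member VIM, the filament protein vimentin, stood at 4.56 ± 6.8 CPM on 32 kPa and 21.7 ± 7.88 CPM on 0.5 kPa, with 0.628 CPM in the R libraries. Markers of other cell types had a median of -2.05 over 14 (camera adjusted p 4.29e-07, and adjusted p = 0.282 with an estimated correlation). Its member PTPRC averaged 33.3 ± 11.8 CPM on 0.5 kPa, whereas the fibroblast gene COL1A1 was at 43 CPM in the R libraries and 41.9 CPM in the rest. On these last lists 0 genes passed, over all genes or adjusted over the list alone.

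The immune lists were also tested on their genes above 1 CPM in the R libraries, which can still hold blood-cell reads in the other libraries. Fitted on that set, antigen presentation genes had a median of -0.42, interferon-stimulated genes of -0.19 and NF-kappaB targets of -0.21, and with the block the list tests gave adjusted p of 1.57e-09, 1.29e-06 and 8.45e-05. With the block over all genes these 3 lists had adjusted p = 0.359, 0.317 and 0.451 with an estimated correlation. The covariate alone over all genes left interferon-stimulated genes passing (adjusted p 0.00121) and the other 2 lists lower without passing (0.215 and 0.471). Once it joined the block, interferon-stimulated genes passed (adjusted p 0.035) at the preset correlation, while the direction of the other 2 lists turned upward without passing (0.63 and 0.602). Neither the basal and mesenchymal list nor the markers of other cell types passed with the covariate (0.219 and 0.738) or with both (0.485 and 0.835), and the markers turned upward in each. Adjusted over the list alone with the block, 11 antigen presentation genes, 6 interferon-stimulated genes, 8 NF-kappaB targets and 5 basal and mesenchymal genes were lower.

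Ribosomal protein genes were slightly lower on 32 kPa, with 74 of 79 negative and a median of -0.12 (camera adjusted p 3.3e-09, and adjusted p = 0.647 with an estimated correlation). RPS14 measured 1284 ± 75.9 CPM against 1891 ± 425 CPM (SD, n = 3 each). On 0.5 kPa replicate 1 stood at 1401 CPM, near the 32 kPa libraries (1197 to 1329), and replicates 2 and 3 at 2100 and 2171 CPM. The blood-cell share was 0.0749% in replicate 1 and 0.1422% and 0.1645% in replicates 2 and 3. Nuclear-encoded respiratory chain genes had a median of -0.09, with 64 of 75 negative (camera adjusted p 3.32e-07, and adjusted p = 0.632 with an estimated correlation). Estrogen-induced genes had a median of 0.09 over 38 (camera adjusted p 0.0128, and adjusted p = 0.635 with an estimated correlation), and luminal identity genes a median of 0.12 over 20 (camera adjusted p 0.0399, and adjusted p = 0.614 with an estimated correlation). The luminal transcription factor gene GATA3 measured 1257 ± 56.7 and 1114 ± 44.5 CPM. Under the blood-cell covariate the ribosomal list turned upward without passing (adjusted p 0.521) and the respiratory chain list was called higher (0.00432), while the estrogen-induced and luminal lists passed upward again (4.73e-08 and 0.000159). Under the block and the covariate the ribosomal list was called lower (0.00149), and the respiratory chain, estrogen-induced and luminal lists kept their direction without passing (0.185, 0.676 and 0.493). No member of these 4 lists passed over all genes or adjusted over the list alone, while with the block 6 ribosomal protein genes and 10 respiratory chain genes were lower adjusted over the list alone. PGR (log2 fold change 0.2, SE 0.15), TFF1 (-0.28, SE 0.19), MKI67 (0.15, SE 0.07), HMGCS1 (-0.01, SE 0.14), CCN2 (0.5, SE 0.41) and ANKRD1 (0.21, SE 0.51) did not pass either.

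The smallest p on the lower side belonged to RN7SL2 (ENSG00000274012, chromosome 14 from 49862550 to 49862849, hg38), a 7SL RNA of the signal recognition particle that normally lacks a poly(A) tail. It measured 142.7 ± 35.2 CPM on 32 kPa and 643.5 ± 220 CPM on 0.5 kPa (SD, n = 3 each), with a log2 fold change of -2.17 (SE 0.26) and an edgeR adjusted p of 0.153. Its near-identical 7SL copies make the level uncertain. ITPKB-IT1, AHSP, DGKG and TSPAN2 followed, each at or below 1.53 CPM in both groups (adjusted p from 0.315 to 0.35). AHSP, a red-cell hemoglobin chaperone, was at 0 in the pooled R libraries. On the higher side the smallest p belonged to the low-abundance RNAs HNRNPK-AS1, CERS6-AS1 and SNORA22, to the transcription factor gene ZFHX3 (176 ± 2.72 CPM against 147.2 ± 7.29) and to the synaptotagmin gene SYT7 (51 ± 3.96 against 42.7 ± 0.79), with adjusted p of 0.474 or 0.498. The antisense RNAs are uncertain because strand use in the counting is not given. With the replicate block edgeR called 1 gene, RN7SL2 (log2 fold change -2.15, adjusted p 0.0041). It did not pass with the block and the blood-cell covariate (-1.57, edgeR adjusted p 0.647) or with the covariate alone (-1.27, 0.999). With the block on the genes above 1 CPM in the R libraries edgeR called 348, of which 294 were lower on 32 kPa. Without 32 kPa replicate 3 it called 988 genes, including all 188 blood-cell genes, and without 0.5 kPa replicate 1 it called 13.

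Comparing TC with 0.5 kPa sets plastic, for which the labels give no rigidity, against the softer gel. AMOTL2, a junctional scaffold and YAP/TAZ target, rose from 63.2 ± 7.63 to 123.2 ± 2.89 CPM (SD, n = 3 each), a log2 fold change of 0.96 (SE 0.08, edgeR adjusted p 0.004). DLC1, a Rho GTPase-activating protein of focal adhesions, rose from 24.2 ± 3.21 to 50.5 ± 2.44 CPM (log2 fold change 1.06, SE 0.09, adjusted p 0.004), and COL12A1, a collagen XII chain, from 51.7 ± 10.6 to 157.6 ± 36.5 CPM (1.61, SE 0.26, adjusted p 0.0408). MUC5AC, a secreted mucin, fell from 13.5 ± 1.85 to 5.41 ± 0.0961 CPM (-1.32, SE 0.16, adjusted p 0.0161), and AKR1C3, an aldo-keto reductase that acts on steroids and prostaglandins, from 10.7 ± 3.28 to 3.36 ± 0.366 CPM (-1.67, SE 0.23, adjusted p 0.024). ESR1 measured 193.4 ± 27.6 CPM on TC and 191.9 ± 16.4 CPM on 0.5 kPa, a log2 fold change of 0.01 (SE 0.13). In all, 60 genes passed in edgeR, 26 higher and 34 lower on TC, and 13 of them by more than 2-fold.

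Further rises were those of PSG9, a pregnancy-specific glycoprotein (log2 fold change 2.04), HTR1E, a serotonin receptor (1.54), and SEMA3D, a secreted semaphorin (1.47). The matrix proteins HMCN1 (1.07) and EFEMP1 (0.96), the focal adhesion protein TNS3 (1.33) and the growth factor receptor FGFR2 (0.95) rose too, and edgeR adjusted p ran from 0.00805 to 0.0447. Further falls were those of AKR1C2, a neighbour and close copy of AKR1C3 (-1.42), HHIPL2 (-1.37), CACNB2, a calcium channel subunit (-1.22), and the non-coding LINC02967 (-1). The surface glycoprotein CEACAM5 (-0.94), the thioredoxin reductase TXNRD1 (-0.92), the mucin-like PARM1 (-0.9) and the calcium-binding S100P (-0.87) fell too, with adjusted p from 0.0161 to 0.0451. AMOTL2 (ENSG00000114019) is on chromosome 3 from 134355874 to 134375479, DLC1 (ENSG00000164741) on chromosome 8 from 13083361 to 13604610, and COL12A1 (ENSG00000111799) on chromosome 6 from 75084326 to 75206051. MUC5AC (ENSG00000215182) is on chromosome 11 from 1157953 to 1201138 and AKR1C3 (ENSG00000196139) on chromosome 10 from 5035354 to 5107686 (hg38), and all 5 are annotated as protein-coding. Of the 60 genes, 59 met the rule for named genes.

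**Figure D2:**
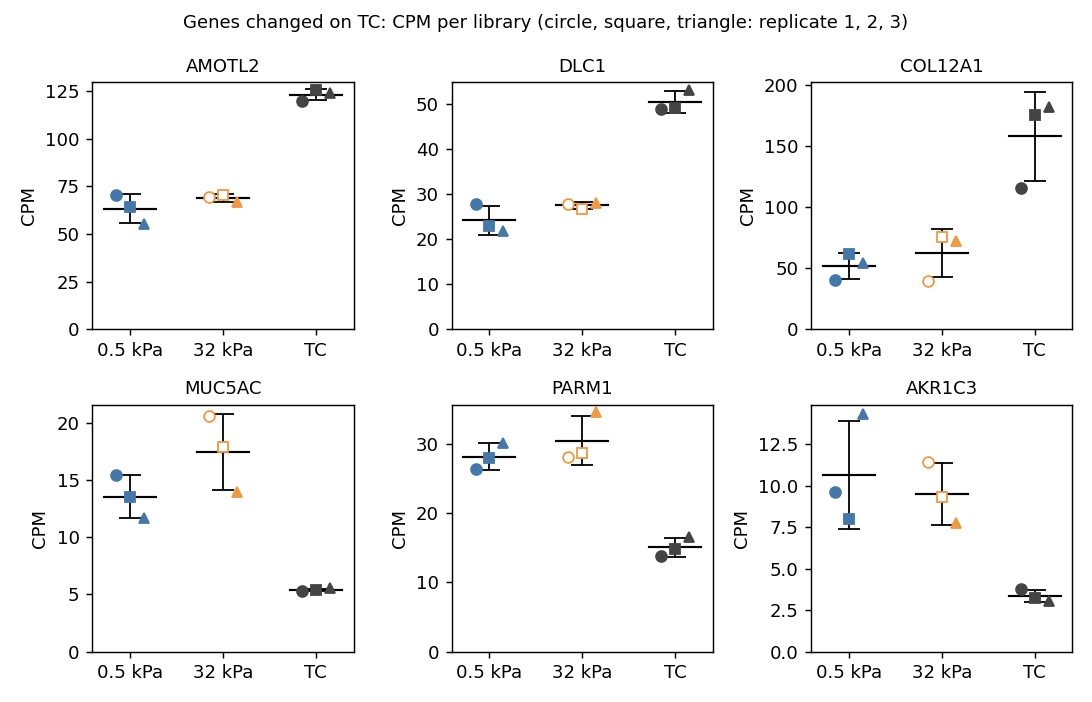
Level in CPM of AMOTL2, DLC1, COL12A1, MUC5AC, PARM1 and AKR1C3 in each library of the 0.5 kPa, 32 kPa and TC groups (circle, square and triangle for replicates 1, 2 and 3, open symbols for the R libraries). Bars are the mean ± SD of 3 libraries. All 3 TC libraries lie above all others for AMOTL2, DLC1 and COL12A1 and below all others for MUC5AC, PARM1 and AKR1C3.

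Lists of YAP/TAZ, actin and adhesion genes were called higher on TC at the preset correlation only, with few members passing over all genes. YAP/TAZ targets had a median log2 fold change of 0.42, with 16 of 19 positive (camera adjusted p 4.27e-07, and adjusted p = 0.28 with an estimated correlation). AMOTL2 alone passed over all genes, 9 were higher adjusted over the list alone, and with the replicate block 9 passed over all genes. TGFB2, a secreted growth factor, measured 9.22 ± 3.13 CPM on 0.5 kPa and 28.4 ± 8.45 CPM on TC (edgeR adjusted p 0.0522, blocked 0.000293), and CCN1 13.1 ± 2.75 and 24.7 ± 6.5 CPM (0.0822, blocked 0.00526). CCN2 measured 3.23 ± 1.72 and 10.9 ± 5.68 CPM (0.0995, blocked 0.00454) and ANKRD1 0.439 ± 0.0339 and 2.7 ± 1.66 CPM (0.0747, blocked 0.0062). In the SRF/MRTF actin list (median 0.1 over 23, camera adjusted p 0.00252, and adjusted p = 0.241 with an estimated correlation), the smooth-muscle actin gene ACTG2 rose from 0.134 ± 0.0414 to 1.48 ± 0.0862 CPM (adjusted p 0.0204). Adjusted over the list alone 5 were higher and 1 lower, and with the block 5 were higher over all genes. The filamin gene FLNA, ACTB and the myosin gene MYH9, with log2 fold changes of 0.44, 0.35 and 0.31, passed with the block alone. Among integrin and focal adhesion genes (median 0.1 over 31, camera adjusted p 0.00225, and adjusted p = 0.241 with an estimated correlation), TNS3 passed over all genes and 2 adjusted over the list alone, and 7 passed with the block.

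DNA replication genes were higher on TC by small amounts, with 37 of 37 positive and a median of 0.27 (camera adjusted p 1.66e-17, and adjusted p = 0.28 with an estimated correlation). Over all genes 0 passed in edgeR, 23 were higher adjusted over the list alone, and 27 passed over all genes with the block. The exonuclease gene EXO1 measured 46 ± 2.91 CPM on TC and 35.6 ± 1.88 on 0.5 kPa, and the helicase gene MCM4 249.9 ± 18.4 and 198.4 ± 4.69 CPM (SD, n = 3 each). Mitotic genes had a median of 0.14, with 30 of 35 positive (camera adjusted p 3.32e-07, and adjusted p = 0.586 with an estimated correlation). Of these 0 passed over all genes, 5 adjusted over the list alone and 14 over all genes with the block, and the proliferation marker MKI67 measured 631.7 ± 43.2 and 480.9 ± 30.2 CPM (adjusted p 0.0567, blocked 0.0117). Replication histone genes, whose mRNAs normally lack a poly(A) tail, went the other way, with 44 of 49 negative and a median of -0.38 (camera adjusted p 6.29e-10, and adjusted p = 0.241 with an estimated correlation). H4C8 (18 ± 0.901 against 26.7 ± 2.01 CPM) and H2BC8 (17.5 ± 0.917 against 25.5 ± 1.69 CPM) fell, 16 were lower adjusted over the list alone, and 15 passed with the block.

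Cholesterol synthesis genes were lower on TC, with 22 of 24 negative and a median of -0.22 (camera adjusted p 1.59e-08, and adjusted p = 0.28 with an estimated correlation). In edgeR 0 passed over all genes, 8 were lower adjusted over the list alone and 14 passed over all genes with the block. Among them were FDFT1, squalene synthase (158.5 ± 3.11 CPM against 199.1 ± 15), and HMGCS1, the enzyme that makes HMG-CoA (233.7 ± 30.5 against 284.4 ± 45.8, blocked adjusted p 0.0075). Estrogen-induced genes were mixed, with a median of 0.07 (camera adjusted p 0.0152, and adjusted p = 0.638 with an estimated correlation). The carbonic anhydrase CA12 (log2 fold change 0.59), the transcription factor MYBL1 (0.47) and the secreted CCN5 (0.79) rose, 7 were higher and 1 lower adjusted over the list alone, and with the block 11 were higher and 2 lower. TFF1, a secreted trefoil peptide, measured 2935 ± 437 CPM on TC and 4952 ± 1310 on 0.5 kPa (adjusted p 0.117, blocked 0.0023), while GREB1 (0.09, SE 0.08) and PGR (-0.07, SE 0.15) did not pass in either fit. ATF4 targets had a median of 0.14 over 26 (camera adjusted p 0.0197, and adjusted p = 0.241 with an estimated correlation), with 0 passing over all genes, 3 higher and 1 lower adjusted over the list alone, and 8 higher and 2 lower with the block. The asparagine synthetase gene ASNS measured 50.1 ± 1.59 and 39.5 ± 1.89 CPM. Hypoxia genes had a median of -0.19 over 22 (camera adjusted p 0.0276, and adjusted p = 0.28 with an estimated correlation), with CA12 higher and NDRG1 lower (log2 fold change -0.71, edgeR adjusted p 0.0408), over all genes and adjusted over the list alone, and 2 higher and 5 lower with the block. Extracellular matrix genes passed as a list with the block (camera adjusted p 0.0136, and adjusted p = 0.451 with an estimated correlation, against 0.0629 without the block), and had COL12A1 higher over all genes, 2 higher adjusted over the list alone, and 7 higher and 1 lower with the block.

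Among the 85 interleukin genes, CISH, a feedback inhibitor of cytokine receptors, rose from 15.5 ± 0.433 to 23.2 ± 0.675 CPM (SD, n = 3 each; log2 fold change 0.59, SE 0.08, edgeR adjusted p 0.0221). STAT6, the transcription factor of interleukin 4 and 13 signalling, fell from 96.7 ± 3.76 to 70.8 ± 1.4 CPM (-0.45, SE 0.05, adjusted p 0.0161). Adjusted over the list alone 2 were higher, CISH and the kinase gene JAK1, and 5 lower, STAT6, PTPN6, IL17RC, IL6R and IL17RE. With the replicate block 4 were higher and 6 lower over all genes, adding to these the cytokine gene LIF (7 ± 1.94 CPM on 0.5 kPa, 11.3 ± 1.71 on TC, blocked adjusted p 0.047), SOCS3 and SOCS2. IL6R measured 14.9 ± 2.8 CPM on TC and 25.6 ± 2.65 on 0.5 kPa (adjusted p 0.0938, blocked 0.0182), and IL17RC 24.7 ± 0.988 and 34.3 ± 3.75 CPM (0.0522, blocked 0.0101). IL20 (log2 fold change 0.45), IL24 (0.39), IL17RB (0.5), IL1R1 (0.08), IL1RAP (-0.23), IL6ST (-0.07) and STAT3 (-0.11) passed in neither fit. As a list, the receptors had a median of -0.4 over 33 (camera adjusted p 0.015, and adjusted p = 0.614 with an estimated correlation), where the blood-cell genes had -1.19 and the 21 receptors above 1 CPM in the R libraries, fitted with the genes of that set, -0.14. The list turned upward without passing under the blood-cell covariate (adjusted p 0.349) and under the block and the covariate (0.641). With the block and a covariate for the blood-cell share, which leaves 3 residual degrees of freedom, 0 interleukin genes passed. The fold of CISH then went from 0.59 (SE 0.06) to 0.56 (SE 0.11), that of STAT6 from -0.45 (SE 0.04) to -0.38 (SE 0.07) and that of IL6R from -0.78 (SE 0.15) to -0.27 (SE 0.12).

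Among the other immune lists 3 were lower on TC, again beside a lower share of blood-cell genes. Antigen presentation genes had a median of -0.41 over 15 (camera adjusted p 1.1e-05, and adjusted p = 0.411 with an estimated correlation). Interferon-stimulated genes had a median of -0.28 over 38 (camera adjusted p 0.000281, and adjusted p = 0.489 with an estimated correlation), and NF-kappaB targets one of -0.28 over 18 (camera adjusted p 0.014, and adjusted p = 0.638 with an estimated correlation). The exonuclease gene ISG20 (log2 fold change -0.85, edgeR adjusted p 0.024) passed over all genes, and adjusted over the list alone 5 antigen presentation genes, 1 interferon-stimulated gene and 0 NF-kappaB targets were lower. With the block the counts were 2, 1 and 1 over all genes. Under the block and the covariate none of these 3 lists passed, with antigen presentation genes and NF-kappaB targets turned upward (camera adjusted p 0.835 and 0.331) and interferon-stimulated genes still lower (0.107). With the covariate alone interferon-stimulated genes were called lower (0.0134), while antigen presentation genes (0.521) and NF-kappaB targets (0.634, turned upward) were not called. Ribosomal protein genes had a median of -0.15 over 79 (camera adjusted p 2.4e-08, and adjusted p = 0.652 with an estimated correlation) and nuclear-encoded respiratory chain genes of -0.06 over 75 (camera adjusted p 0.0141, and adjusted p = 0.827 with an estimated correlation), with 0 passing in either, over all genes or adjusted over the list alone. With the block 1 ribosomal protein gene was higher and 9 lower, and 4 respiratory chain genes were lower. The ribosomal list was called with the block and the covariate (1.79e-05) but not with the covariate alone (0.145), and the respiratory chain list with neither (0.557, and 0.0585 turned upward). Of all genes, 2915 had an unadjusted p under 0.05. DESeq2 called 894, the replicate block raised the count to 1997 (1149 higher and 848 lower) and DESeq2 with the block gave 2704, while the blood-cell covariate lowered it to 8, or to 39 with the block. In that last fit 14 of the 60 genes passed and all 60 kept their sign, with median folds of -0.61 for the falls and 0.8 for the rises, against -0.66 and 0.78 with the block alone. Single libraries moved it as well, to 389 without 0.5 kPa replicate 1, 335 without 32 kPa replicate 3, 5 or 10 without 0.5 kPa replicate 2 or 3, 7, 6 or 2 without TC replicate 1, 2 or 3, and 38 or 31 without 32 kPa replicate 1 or 2. The 60 genes kept their sign in each of these.

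**Figure D3:**
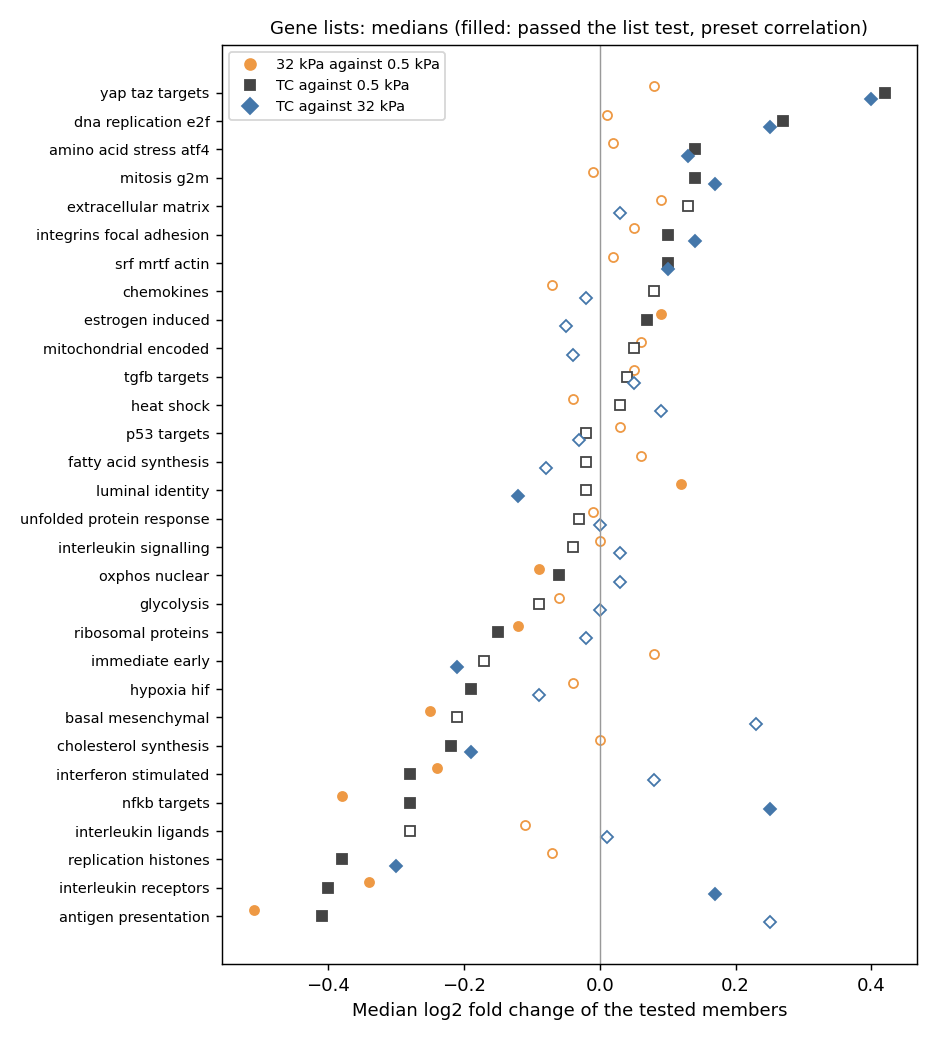
Median log2 fold change (x axis) of the tested members of 30 gene lists (y axis), without the markers of other cell types, in each of the 3 comparisons (circle, 32 kPa against 0.5 kPa; square, TC against 0.5 kPa; diamond, TC against 32 kPa). Filled symbols passed the list test with a preset correlation, and 0 lists passed with an estimated one. YAP/TAZ targets lie highest for TC against 0.5 kPa (0.42) and against 32 kPa (0.4), and DNA replication genes lie at 0.27 and 0.25.

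Comparing TC with 32 kPa sets plastic against the stiffer gel. The mucin gene MUC5AC fell from 17.5 ± 3.32 to 5.41 ± 0.0961 CPM (SD, n = 3 each; log2 fold change -1.69, SE 0.16, edgeR adjusted p 0.00537). AKR1C3 fell from 9.51 ± 1.85 to 3.36 ± 0.366 CPM (-1.5, SE 0.23, adjusted p 0.0444) and PCDH19, a cell adhesion protocadherin, from 29.9 ± 0.454 to 17.2 ± 0.208 CPM (-0.8, SE 0.06, adjusted p 0.00293). AMOTL2 rose from 68.9 ± 1.89 to 123.2 ± 2.89 CPM (0.84, SE 0.08, adjusted p 0.00537) and DLC1 from 27.6 ± 0.808 to 50.5 ± 2.44 CPM (0.87, SE 0.09, adjusted p 0.00647). SEMA3D (1.53), HTR1E (1.63), TNS3 (1.39), EFEMP1 (0.91), FGFR2 (0.87), the keratin KRT80 (0.71), CCN5 (0.69) and SAMD4A (0.64) also rose, with adjusted p from 0.00537 to 0.0494. The membrane protein ANO7 (-1.49), CACNB2 (-1.37), LINC02967 (-1.02), PARM1 (-1.01), CEACAM5 (-0.97), FAXDC2 (-0.91) and the nuclear protein AFF3 (-0.85) also fell, with adjusted p from 0.00647 to 0.0494. In all 38 genes passed, 16 higher and 22 lower on TC, 10 of them by more than 2-fold.

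DNA replication genes had a median of 0.25, with 37 of 37 positive (camera adjusted p 2.66e-20, and adjusted p = 0.28 with an estimated correlation), and mitotic genes of 0.17, with 34 of 35 positive (camera adjusted p 1.59e-08, and adjusted p = 0.51 with an estimated correlation). Over all genes 0 members of either list passed in edgeR. Adjusted over the list alone 25 replication genes and 0 mitotic genes were higher, and with the block 17 and 12 passed over all genes. EXO1 measured 35.3 ± 0.748 CPM on 32 kPa and 46 ± 2.91 CPM on TC. Replication histones had a median of -0.3 over 49 (camera adjusted p 1.59e-08, and adjusted p = 0.241 with an estimated correlation). H4C8, H2BC21 and H2BC8 fell, with log2 fold changes of -0.63, -0.56 and -0.61, while 13 were lower adjusted over the list alone and 12 passed with the block. YAP/TAZ targets had a median of 0.4 over 19 (camera adjusted p 1.78e-06, and adjusted p = 0.282 with an estimated correlation). Of these AMOTL2 passed over all genes, 5 were higher adjusted over the list alone, and with the block 8 were higher and 1 lower. TGFB2 measured 9.69 ± 2.1 CPM on 32 kPa and 28.4 ± 8.45 on TC (edgeR adjusted p 0.0748, blocked 0.000319). Integrin and focal adhesion genes (median 0.14 over 31, camera adjusted p 0.000207, and adjusted p = 0.241 with an estimated correlation) had TNS3 higher over all genes, 2 adjusted over the list alone and 5 with the block. SRF/MRTF actin genes (0.1 over 23, camera adjusted p 0.00106, and adjusted p = 0.241 with an estimated correlation) had ACTG2 higher over all genes (log2 fold change 2.96, SE 0.41), 6 higher and 2 lower adjusted over the list alone, and 5 higher and 1 lower with the block.

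Cholesterol synthesis genes had a median of -0.19, with 22 of 24 negative (camera adjusted p 2.39e-08, and adjusted p = 0.28 with an estimated correlation), 0 passing over all genes, 4 lower adjusted over the list alone and 12 with the block. Those 12 include lanosterol synthase, LSS, and SQLE, squalene epoxidase. Luminal identity genes had a median of -0.12 over 20 (camera adjusted p 0.00477, and adjusted p = 0.51 with an estimated correlation), with 0 passing over all genes and 2 higher and 5 lower adjusted over the list alone, and with the block 2 higher and 6 lower. The keratin KRT18 measured 6017 ± 337 CPM on TC and 4698 ± 172 on 32 kPa, and the transcription factor FOXA1 377.3 ± 11.5 and 452.9 ± 28.9 CPM. Immediate early genes had a median of -0.21, with 22 of 26 negative (camera adjusted p 0.00049, and adjusted p = 0.614 with an estimated correlation) and 0 passing, over all genes or adjusted over the list alone. With the block 2 were lower, KLF4 and FOSL2, and KLF4 was at 59.9 ± 6.07 and 91.7 ± 15.4 CPM. ATF4 targets had a median of 0.13 over 26 (camera adjusted p 0.0192, and adjusted p = 0.241 with an estimated correlation), with 0 passing over all genes, 1 higher adjusted over the list alone, and 4 higher and 1 lower with the block. From the estrogen-induced list CA12 (log2 fold change 0.48) and CCN5 rose, with 4 higher adjusted over the list alone, 5 higher and 2 lower with the block, and the list as a whole not passing (camera adjusted p 0.616). ESR1 (-0.11, SE 0.13), PGR (-0.27, SE 0.15) and GREB1 (-0.18, SE 0.08) did not pass. Of the TGF-beta targets, ID1, a differentiation inhibitor, fell (-0.74, SE 0.11, edgeR adjusted p 0.034). The list itself had a median of 0.05, with 12 of 20 positive, and with the block 5 were higher and 2 lower.

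Of the 85 interleukin genes, CISH rose from 16.1 ± 0.744 to 23.2 ± 0.675 CPM (log2 fold change 0.53, SE 0.08, edgeR adjusted p 0.0362) and 0 fell. Adjusted over the list alone 2 were higher, CISH and JAK1, and 2 lower, IL17RC and STAT6, and with the replicate block 3 were higher and 4 lower, adding SOCS3, PIAS3 and SOCS2. Where the blood-cell genes had a median of 1.18, the receptor list had a median of 0.17 over 33 (camera adjusted p 0.0197, and adjusted p = 0.614 with an estimated correlation) and the 21 receptors above 1 CPM in the R libraries, fitted with that set, one of 0. NF-kappaB targets (0.25 over 18, camera adjusted p 0.0276, and adjusted p = 0.652 with an estimated correlation, 0.0658 with the block) and markers of other cell types (0.84 over 14, camera adjusted p 0.0032, and adjusted p = 0.614 with an estimated correlation) were higher on TC. Of these 3 lists 0 members passed over all genes, and 1 receptor gene, IL17RC, was lower adjusted over the list alone and with the block. IL6R measured 14.9 ± 2.8 CPM on TC and 15 ± 3.41 on 32 kPa, a log2 fold change of -0.01 (SE 0.18). Of all genes, 1835 had an unadjusted p under 0.05. DESeq2 called 409, the replicate block raised the count to 939 and DESeq2 with the block gave 1433, while a term for the R libraries lowered it to 3 and leaving both out to 0 (909 at an unadjusted p under 0.05), which leaves a single 32 kPa library. It was 863 without 32 kPa replicate 3 (729 higher and 134 lower on TC, all 188 blood-cell genes being among the 863), 13 or 6 without 32 kPa replicate 1 or 2, 11 without 0.5 kPa replicate 2 and 7, 9 or 6 without TC replicate 1, 2 or 3. The 38 genes kept their sign in each of these.

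Interleukin ligands, interleukin signalling, chemokines, extracellular matrix, TGF-beta targets, fatty acid synthesis, glycolysis, the unfolded protein response, heat shock, p53 targets and mitochondrially encoded genes passed the list test without the block or the covariate in no comparison, with camera adjusted p from 0.0594 to 0.983. With the block, the list test called extracellular matrix genes higher and glycolysis genes lower on 32 kPa (adjusted p 0.0262 and 0.0135) and on TC (0.0136 and 0.0292) than on 0.5 kPa. In TC against 32 kPa it called fatty acid synthesis genes lower (0.0262) and heat shock genes higher (0.0318), and in TC against 0.5 kPa immediate early genes lower (0.0262, against 0.0507 without the block). Joined with an estimated correlation, the blocked test called 0 lists. With the blood-cell covariate in place of the block, extracellular matrix genes were called lower (0.000498) and glycolysis genes higher (0.0231) on 32 kPa than on 0.5 kPa, against the blocked direction, and with both neither passed (0.63 and 0.864). On TC against 0.5 kPa the covariate called neither and turned both directions (0.471 each), and with the block as well extracellular matrix genes were called higher (0.035) and glycolysis genes were not called (0.493). The fatty acid, heat shock and immediate early calls were lost with both (0.117, 0.091 and 0.27), the last turned upward. The median and the list test differed in sign, without passing, for estrogen-induced genes and chemokines in TC against 32 kPa, chemokines in TC against 0.5 kPa, and the integrin, mitosis and p53 lists in 32 kPa against 0.5 kPa.

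The blood-cell covariate changed which lists were called. Of the 10, 16 and 13 lists called between the gels, for TC against 0.5 kPa and for TC against 32 kPa, 3, 10 and 10 were called in the same direction with the covariate, and 2, 8 and 9 with the block and the covariate. Those 8 are the YAP/TAZ, SRF/MRTF actin, integrin, mitosis, DNA replication, cholesterol, ribosomal and histone lists. Beyond the lists described above, hypoxia, ATF4 and estrogen-induced genes lost their call in that fit for TC against 0.5 kPa (adjusted p 0.185, 0.054 and 0.457), and interleukin receptors, NF-kappaB targets, ATF4 targets and markers of other cell types for TC against 32 kPa (0.237, 0.63, 0.0766 and 0.091). Lists not called without these terms were called too. Between the gels the block and the covariate called TGF-beta targets (3.89e-05), immediate early genes (6.42e-17) and p53 targets (0.0025) higher and DNA replication genes lower (0.00049) on 32 kPa. With the covariate alone TGF-beta targets were lower (0.0161) and replication (0.00643), immediate early (2.93e-07) and mitotic genes (3.13e-11) higher. For TC against 0.5 kPa the block and the covariate also called TGF-beta targets higher (0.00131), and for TC against 32 kPa hypoxia genes (0.0406) and p53 targets (0.0279) lower. The covariate alone also called p53 targets lower (0.0202) and markers of other cell types higher (0.0134) for TC against 0.5 kPa, and extracellular matrix genes higher (0.0127) and ribosomal protein genes lower (0.00785) for TC against 32 kPa.

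The changes from 0.5 kPa to 32 kPa and from 0.5 kPa to TC correlated across the 18767 genes with r = 0.7, and genes are not independent replicates. Both comparisons use the same 0.5 kPa libraries, and unchanged groups simulated against them gave r = 0.51 (SD 0.016). The covariance was 0.173 against a simulated 0.0818, a difference of 0.0912. That simulation has no effect shared by replicate number. With the block, and shared replicate effects in the simulation, r was 0.65 against 0.51 (SD 0.016) over all genes and 0.54 against 0.51 (SD 0.011) over the genes above 1 CPM in the R libraries. The 3 shared libraries cannot be split into 2 sets of 2, so how much of the excess comes from them is not measured, and the blood-cell genes are lower in both comparisons. With 0 genes passing between the gels, 0 passed in both. Of the 60 genes that passed in TC against 0.5 kPa, 41 had the same sign in 32 kPa against 0.5 kPa, and all 60 had the same sign in TC against 32 kPa, where 35 passed, among them AMOTL2, DLC1 and MUC5AC. These 2 comparisons share the TC libraries, which by itself gives called genes like signs. Over all genes they correlated with r = 0.09, below the 0.52 (SD 0.014) of simulated unchanged groups, with a covariance of 0.0163 against 0.0845. With the block r was -0.02 against a simulated 0.52 (SD 0.015) over all genes, but 0.6 against 0.53 (SD 0.0097) over the genes above 1 CPM in the R libraries, so the low value depends on the genes below that level.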

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

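The covariate for the blood-cell share, the limit to genes above 1 CPM in the R libraries (32 kPa replicates 1 and 2), and every setting that joins the block with another one were chosen after the results were seen. Unless a reason is given, the cause of a change was not tested. Of 478 values of the genes named as rising or falling in TC against 0.5 kPa 128 were weaker, of 480 in TC against 32 kPa 151, and 0 were reversed. With the size factors of DESeq2, edgeR called 0 genes between the gels (1366 at an unadjusted p under 0.05), 66 for TC against 0.5 kPa and 34 for TC against 32 kPa.

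Genes that passed between the gels numbered 0 in edgeR. They were 1 with the genes above 1 CPM in the R libraries, 159 with DESeq2, and from 0 to 988 when single libraries were left out, highest without 32 kPa replicate 3. Leaving that library out leaves the 32 kPa group with the R libraries alone, which lack the blood-cell RNAs, and all 188 blood-cell genes were then called. For the 85 interleukin genes the 0 became 3 with DESeq2 and 0 to 24 without single libraries.

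For TC against 0.5 kPa the 60 genes became 131 with those 2 groups alone, 262 with a term for the R libraries, 225 without both, 157 over the genes above 1 CPM, 894 with DESeq2 and 8 with a covariate for the blood-cell share. Leaving out single libraries gave 2 (without TC replicate 3) to 389 (without 0.5 kPa replicate 1). The 2 interleukin genes became 5 with a filter of 1 CPM in 3 libraries, 5 with those 2 groups alone, 11 with the R term, 7 without the R libraries, 5 above 1 CPM, 8 with DESeq2, 0 with the covariate and 0 to 10 without single libraries.

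For TC against 32 kPa the 38 genes became 23 with those 2 groups alone, 3 with the R term, 0 without the R libraries, 59 with the covariate, 78 above 1 CPM, 409 with DESeq2 and 6 to 863 without single libraries, highest without 32 kPa replicate 3, where all 188 blood-cell genes were called and 729 of the 863 were higher on TC. Without the R libraries a single 32 kPa library remains, and the 38 genes kept their sign. The 1 interleukin gene became 0 with those 2 groups alone, with the R term or without the R libraries, 2 above 1 CPM, 4 with DESeq2 and 0 to 19 without single libraries.

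The fit with the replicate number as a block takes these numbers to pair the libraries, which the labels do not say. With it the genes called were 1 between the gels, 1997 for TC against 0.5 kPa and 939 for TC against 32 kPa, and the interleukin genes 0, 10 and 7. All 60 and all 38 genes passed with the block too. Over the genes above 1 CPM in the R libraries the block gave 348, 3087 and 1600 genes and 10, 18 and 11 interleukin genes. With the block and the R term it gave 1, 2999 and 82 genes and 0, 29 and 0 interleukin genes, and with the block but without the R libraries 1, 1969 and 25 genes and 0, 25 and 0 interleukin genes. With the block and the covariate, which leaves 3 residual degrees of freedom, 0, 39 and 635 genes and 0, 0 and 6 interleukin genes passed. DESeq2 with the block gave 806, 2704 and 1433 genes and 11, 17 and 13 interleukin genes.

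Gene lists that passed numbered 10 between the gels, 16 for TC against 0.5 kPa and 13 for TC against 32 kPa. With an estimated correlation between members they were 0, 0 and 0, with the lowest adjusted p at 0.241 in each, and also 0, 0 and 0 when the block was added. With the covariate they were 10, 12 and 12, of which 3, 10 and 10 were called before in the same direction and 1, the respiratory chain list between the gels, in the opposite one. With the block and the covariate they were 6, 10 and 11, of which 2, 8 and 9 were called before in the same direction and 4, 2 and 2 are new. Leaving out single libraries gave 9 to 15, 14 to 19 and 13 to 15.

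The correlation of r = 0.7 between the changes to 32 kPa and to TC became 0.67 without a low-count filter, 0.73 with 1 CPM in 3 libraries, 0.45 with the R term, 0.43 without the R libraries, 0.63 with the covariate, 0.55 above 1 CPM, 0.67 with DESeq2 and 0.59 to 0.8 without single libraries. With the block it was 0.65, with block and covariate 0.68, above 1 CPM with block 0.54, with block and R term 0.49, with block but without the R libraries 0.45, and 0.59 in DESeq2 with the block.

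The limits are few libraries, 3 per group, of which 2 in the 32 kPa group differ from all others in depth and in blood-cell RNA, so that the spread within that group mixes surface with library. A term for the R libraries leaves the 32 kPa group resting on 1 library, and the covariate takes up part of any true difference between the surfaces.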

Other observations

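The splits of libraries and the fits that leave out the R libraries were set beforehand. The other tests in this part and the counts of genes called again were chosen after the result was seen.

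Genes of the NRF2 response, which handle oxidants and electrophiles, were lower on TC. The list of 27 tested genes was put together after AKR1C2, AKR1C3, TXNRD1, SLC7A11, ME1 and OSGIN1 were seen to fall, so these 6 genes were set aside. The other 21 belong to the same response and were read in the same libraries, so their test is not independent of that choice. Of the other 21, all had a negative sign in TC against 0.5 kPa, with a median log2 fold change of -0.49 (camera p 1.61e-13, and p = 0.0405 with an estimated correlation). The ferritin gene FTL passed over all genes (-0.56, edgeR adjusted p 0.0408) and 15 passed with the replicate block, among them the heme oxygenase gene HMOX1 (-1.24, blocked adjusted p 0.00732) and the quinone reductase gene NQO1 (-0.83, blocked 0.00832). With the block and the covariate for the blood-cell share, 0 of the 21 passed, while all 21 stayed negative and the median went from -0.45 with the block alone to -0.38. In TC against 32 kPa, which shares the TC libraries, all 21 were negative, with a median of -0.36 (camera p 8.06e-11, and p = 0.0617 with an estimated correlation). Between the gels 18 of 21 were negative, with a median of -0.16 (camera p 0.00346, and p = 0.342 with an estimated correlation). Under that joint fit TC against 32 kPa kept all 21 negative with a median of -0.39 and 7 passing, whereas between the gels 6 of 21 were negative with a median of 0.07, so a fall between the gels does not hold there. Among the genes with the smallest blocked p, chosen after their values were seen, were CXCR4, a chemokine receptor, and COL5A1, a collagen V chain. CXCR4 measured 39.9 ± 13 CPM on 0.5 kPa and 17.7 ± 3.19 CPM on TC (SD, n = 3 each, blocked adjusted p 0.000404). The blood-cell genes had a median log2 fold change of -1.19 there. The fits with the covariate covered CXCR4 too, but their values are not given here, so whether blood-cell reads add to its fall is left open. COL5A1 measured 58 ± 33.2 and 129.3 ± 60.9 CPM (blocked 0.000293) and did not pass without the block.

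Transcripts of blood cells in 7 of 9 MCF7 libraries are likely not a response of the cells to the surface. With the genes chosen from the 0.5 kPa and TC libraries and 1 R library, their share in 32 kPa replicate 3 was at the lower of 2 such tests 150 times that of the other R library, grown on the same surface. Whole-blood RNA is unlikely too, since HBB, the beta-globin gene, had 0.0146 counts per count of ALAS2, unless globin mRNA had been removed. The lowest correlation of their log2 levels between any of the 7 libraries was 0.943 and the median 0.953. In 300 sets of other genes of like level the lowest ran from 0.788 to 0.879 and the median from 0.91 to 0.938. Their proportions were thus steadier than those of other genes, which is consistent with foreign RNA of one composition but does not show where or how it came in. The test could not separate a source in the laboratory from one in sequencing, and a library of blood RNA processed alongside would settle it.

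The lower interleukin receptor list on 32 kPa may come in part from those reads. Receptor genes above 1 CPM in the R libraries had a median log2 fold change of -0.06, far from the -2.4 of the blood-cell genes, though the choice of those genes by the R libraries adds to that gap. Over all 33 genes the list lost its call with the covariate for the blood-cell share (adjusted p 0.634) and with the block and the covariate (0.522), where the median went from -0.34 with the block alone to -0.03, though the covariate also takes up part of any true difference. Whether lower expression in the cells adds to it stays open. The list test on the genes above 1 CPM gave an adjusted p of 0.0665 with the block, which decides neither way. That filter removes any receptor gene switched off on 32 kPa, which leans against a response of the cells. It also keeps blood-cell reads in genes that the R libraries express, which leans the other way. IL6R, at 13.1 CPM in the R libraries, went from -0.79 (SE 0.15) to -0.05 (SE 0.15) when the covariate joined the block, a change that either reading allows.

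The differences of TC from both gels, such as AMOTL2, DLC1, COL12A1 and MUC5AC, are unlikely to come from blood-cell reads alone. Less such RNA on TC than on 0.5 kPa cannot raise genes. All 34 genes lower on TC than on 0.5 kPa stood above their TC level in the R libraries, which lack it (median log2 ratio 0.65, SD 0.37). These genes were chosen for being lower on TC, and the same TC libraries enter the ratio, which favours such a gap. With the block and the covariate all 60 genes called kept their sign and 14 passed, against 6 with the covariate alone. The R libraries are in neither group of TC against 0.5 kPa. Their depth or handling can reach those calls only through the shared spread, the gene filter and the normalization. Without them 54 of the 60 genes were called again, among 225 in all, of which 37 were blood-cell genes. Such a repeat is favoured by the design and is weak evidence. Against 32 kPa a single library, replicate 3, remains without the R libraries, which keeps an effect of their depth or handling open. All 38 genes kept their sign and lay outside the TC range there, but replicate 3 was itself among the libraries that called them. Median folds were then -0.7 for falls and 0.83 for rises, against -0.77 and 0.77 with the R libraries. Rigidity alone might order the surfaces from 0.5 kPa over 32 kPa to TC, and 41 of the 60 genes had the same sign between the gels, but that count shares the 0.5 kPa libraries and decides nothing, and coating and plate material were not tested. 

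With 3 libraries against 3 there are 10 ways to split them, so the share of splits that do as well as the real one is never under 0.1. Between the gels the real split called 0 genes and so did all others, so 10 of 10 did as well. In TC against 0.5 kPa the real split called 60 and the highest other 0, so 1 of 10 did as well, and in TC against 32 kPa the real split called 38 and the highest other 0, again 1 of 10. Of the splits, 4, the real one included, part all pairs of replicate numbers. With the block the real split called 1, 1997 and 939 genes and the highest of the others 0. So 1 of 4 did as well each time, which is the lowest share that 4 splits allow and cannot decide the question.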
